A study of Mus musculus with 10 samples.

How the data were processed

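CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA beside a histone mark, was run on brain parenchymal macrophages sorted by flow cytometry from Ms4a3Cre:R26-tdTomato mice. As background, Ms4a3-driven Cre marks the progeny of granulocyte-monocyte progenitors, so that cells which once passed through that stage carry the red reporter. The labels divide the 10 libraries into YSM and MDM samples. MDM stands for monocyte-derived macrophages in the series title, and YSM is not spelled out in the labels. Library names give H3K27ac, a mark of active promoters and enhancers, for 4 YSM and 4 MDM libraries. They give H3K27me3 for 1 YSM and 1 MDM library, whereas the series text names an antibody to another mark, H3K4me3. These 2 libraries were not analysed here. All libraries carry the treatment label DR-3x, which the labels do not explain.

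The values start from 2 lists of H3K27ac regions, 1 named for MDM and 1 for YSM, which the authors deposited after a differential test between the groups. Each list gives a chromosome, a start, an end, a region name and a score. The score in the lists deposited by the authors is a whole number with no stated meaning, equal to 1 in 421 of 428 MDM regions and 871 of 892 YSM regions. The lists have no header, and the threshold, the scaling and the direction of the test are not given in the sources used here. A list named for a group was read as the regions with higher H3K27ac in that group. Per the submitters' processing notes, which give no role or order, the tools were Trimmomatic 0.39, Bowtie2 2.2.5, Picard and HOMER, and the genome build was mm10. Read depth, fold changes, p-values and values per library were not used here, so no error between libraries can be given for any region. Whether the 4 libraries of a group came from separate animals is not stated. Every p-value below compares lists of regions or genes, not animals, and every interval covers counting error only.

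Positions are printed from 1, with the first base of each deposited start shifted by 1. Genes came from a RefSeq gene table of GRCm38.p6, the same assembly as mm10, with 21887 protein-coding genes. The table gives the start and end of each gene and no strand, so the transcription start could not be told from the other end. The distance planned from a region's midpoint to the nearest transcription start was therefore replaced by the distance to the nearest end of a protein-coding gene, and a region counted as near a promoter may lie at the 3' end of a gene. Exons, introns and untranslated regions were not separated, and "inside a gene" means between its annotated start and end. A region was assigned to the gene with the nearest end if that end lay within 100 kb. A comparison of 25 sequence motifs planned before the data were examined was not run, because no genome sequence was used here.

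The main comparisons, the 26 gene lists and the rule for named genes were fixed before the data were examined. The rule named, per list, the 10 genes with the most assigned regions, ties going to the smaller distance and then the symbol. It also named the members of the lists for microglia identity, engrafted macrophages, lineage reporters and macrophage transcription factors with an assigned region, at most 12 per list, and the genes of the 5 highest scores per list. The last part, up to 4 members of any other gene list that passed its test, named no gene. Of 874 distinct symbols in the 26 lists, 7 had no protein-coding gene in the table. Other genes, named as members of a list that held few genes or as the gene at a single region, were chosen after their values were seen.

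Each gene list was tested with Fisher's exact test, two-sided, between the genes with regions of the MDM list only and those with regions of the YSM list only, with Benjamini-Hochberg adjustment over the 26 lists and a threshold of 0.05. The background was the genes with a region in either list, because regions tested by the authors and not listed are unknown. Log2 odds ratios were computed after a small constant was added to every count. They therefore stay finite at counts of 0 and differ from the plain ratio. The share of regions within 1 kb of a gene end and the share on the X chromosome were also compared with Fisher's exact test, two-sided. Genes with regions of both lists, and the share of regions whose nearest other region within 50 kb belonged to the same list, were tested by 10000 permutations of list membership over regions, two-sided. The smallest p these can give is 1e-04. Shares carry exact Clopper-Pearson 95% intervals, and differences of shares carry normal 95% intervals. Width was not tested because every region is 2001 bp long.

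The gene list test was tested on simulated data with 598 genes, as many as entered the real comparison. With 20 or 30 members of 1 list planted among the YSM genes, the list was called in 100 of 100 draws each. With 5, 10 or 15 planted members it was called in 0 of 100 draws, and no other list was called in any draw. Planted among the fewer MDM genes, 8 or 10 members were called in 100 of 100 draws, and 3 or 5 in 0 of 100. No other member of the planted list entered either side, so its Fisher's exact p was the same in every draw. The calls therefore mark a limit for members all on 1 side and are not a rate of detection.

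Alternatives were windows of 2.5 and 5 kb, distance from the region edge, all gene types, limits of 10 kb or none on the assignment, gene bodies with 5 kb flanks extended by up to 1 Mb, joining of regions of 1 list within 12.5 kb, regions in place of genes as the unit, and random genes on the same chromosomes. Others were added after the data were seen: assignment to the nearest gene body, random positions, the first part of each list in file order, up to its middle, regions with a name number of 2 or more, and lists without the regions of single loci. Statistics used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.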

Results

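H3K27ac was profiled by CUT&Tag in 4 YSM and 4 MDM libraries of sorted mouse brain parenchymal macrophages. The data analysed are the regions that the authors' test separated between these groups: 428 regions listed for MDM and 892 for YSM, each 2001 bp long. The comparison asks where in the genome brain macrophages derived from monocytes carry more or less of this mark of active chromatin than YSM macrophages of the same tissue. The lists give no level or fold for a region, and their depth is unknown.

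YSM regions outnumbered MDM regions by 2.08 to 1, and the YSM list held 67.6% of all 1320 regions. An even split was excluded by a two-sided exact binomial test over regions (p = 5.86e-38). Neighbouring regions are not independent, since 33.6% of MDM and 37.8% of YSM regions overlapped another region of their own list. After nearby regions of 1 list were joined, 321 MDM and 615 YSM groups remained, a ratio of 1.92. No region of one list overlapped a region of the other, and the closest pair of opposite lists lay 63.8 kb apart.

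The MDM list was led by Dach1, which encodes a transcriptional cofactor, with 8 assigned regions in 3 groups, the nearest to a gene end at chr14:98168834-98170834 (mm10), 0.069 kb outside the gene. Fshr, the receptor of follicle-stimulating hormone, had 6 regions (nearest chr17:88980012-88982012), and Adam19, a membrane metalloprotease, had 5, all inside the gene (nearest chr11:46061020-46063020). Fam110b (nearest chr4:5643059-5645059, 0.050 kb from a gene end), Serpinb2, which encodes plasminogen activator inhibitor 2 (chr1:107524868-107526868, 0.268 kb), and Lrrk2, a kinase gene mutated in familial Parkinson disease (chr15:91672088-91674088, 0.297 kb), had 4 each. The remaining genes of the leading 10 had 3 regions each: Tmtc1 (chr6:148443867-148445867), the phospholipase C gene Plcb4 (chr2:135657797-135659797), the vasoactive intestinal peptide receptor Vipr2 (chr12:116144395-116146395) and Adgre5, which encodes the leukocyte adhesion receptor CD97 (chr8:83747098-83749098). The 3 regions of Vipr2 formed 1 group, and so did the 3 of Adgre5, which lay outside the gene, the nearest 6.79 kb from its end. None of these 10 genes had a YSM region. Most MDM genes, 134 of 201, had 1 region.

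The YSM list was led by Klf12, a Krüppel-like transcription factor, with 12 regions in 4 groups, 11 of them inside the gene and the nearest at chr14:100285055-100287055, 0.164 kb from its end. Adamts16, a secreted metalloprotease, had 11 regions (nearest chr13:70840660-70842660) in 5 groups, more groups than Klf12. Tcim, a regulator of Wnt signalling, had 8 regions (nearest chr8:24437903-24439903) in 2 groups. A run of 7 regions at Tcim, from 24418784 to 24440168 on chromosome 8, was the group with the most regions in either list. It spanned 21.4 kb, less than a group of 6 regions at Klf12, which spanned 27.2 kb. Magi1, a scaffold protein of cell junctions (nearest chr6:94282795-94284795), and the receptor phosphatase Ptprm (chr17:67353725-67355725) had 7 each. The collagen gene Col25a1 (chr3:130179388-130181388), the retinoid X receptor gene Rxrg (chr1:167597470-167599470) and the glutamate transporter gene Slc1a3 (chr15:8641480-8643480) had 6 each. Nova1, a splicing regulator (chr12:46818529-46820529), and Jam2, a junctional adhesion molecule (chr16:84773216-84775216), had 5 each. None of these 10 genes had an MDM region, and 256 of 399 YSM genes had 1 region.

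**Figure D1:**
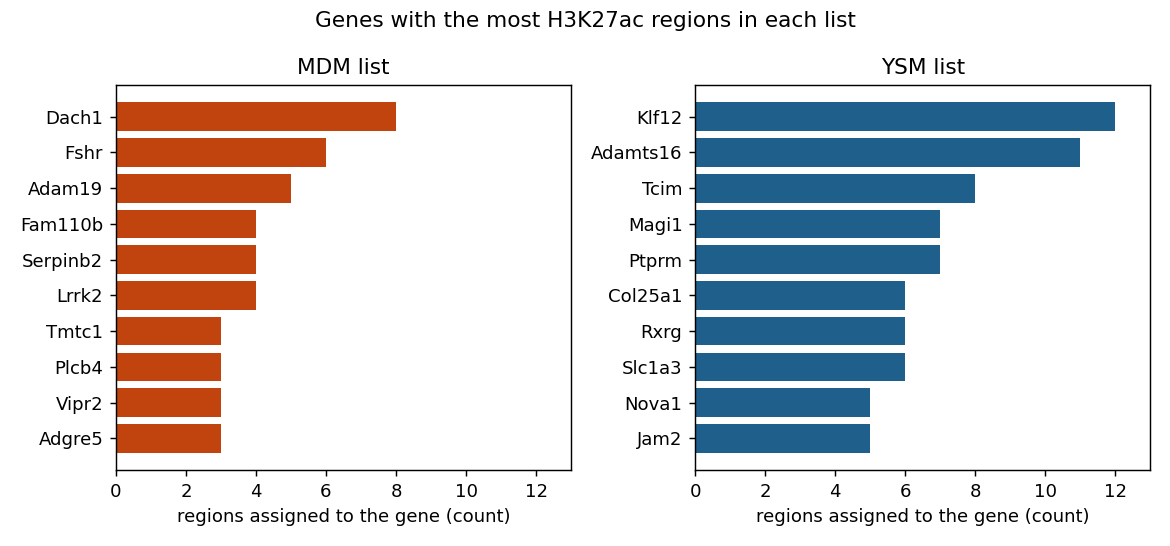
Number of listed H3K27ac regions (horizontal axis, count) assigned to each of the 10 genes with the most regions, in the MDM list (left) and the YSM list (right); each bar is 1 gene. The longest bars are Dach1 with 8 MDM regions and Klf12 with 12 YSM regions. Overlapping regions are counted separately.

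Sall1, the transcription factor that defines the identity of resident microglia, had YSM regions and no assigned MDM region. Of 5 YSM regions within 100 kb of the gene ends, the nearest lay at chr8:89042804-89044804, inside the gene and 0.358 kb from its end. Between 88.6 and 89.5 Mb the YSM list held 12 regions, for all of which Sall1 was the nearest protein-coding gene. Among them was a group of 5 from 89382723 to 89405487, between 340 and 360 kb from the gene end. The MDM list held 1 region in the same interval, inside Nod2, a receptor of bacterial muramyl peptides, at chr8:88667769-88669769.

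**Figure D2:**
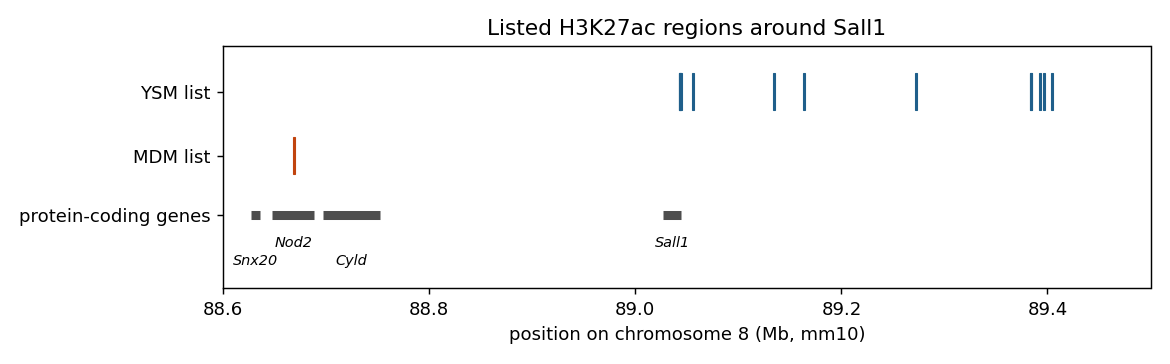
Listed H3K27ac regions of the MDM and YSM lists and protein-coding genes from 88.6 to 89.5 Mb of chromosome 8 (horizontal axis, Mb, mm10); each box is 1 region drawn to scale. The 12 YSM regions lie from Sall1 to 360 kb beyond it, and the MDM region lies at Nod2.

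Of the 67 microglia identity genes, 8 had YSM regions and 1 had an MDM region. The YSM members were Sall1, Jam2 with 5 regions, Csmd3 with 4 (nearest chr15:48791966-48793966), the tubulin-binding gene Tppp with 3 (chr13:74008402-74010402), the actin-bundling gene Fscn1 with 2 (chr5:142959244-142961244), Adgrg1, which encodes the adhesion receptor GPR56, with 2 (chr8:94983144-94985144), Sall3 with 2 (chr18:81013225-81015225), and Mcf2l with 1 (chr8:12905665-12907665). The MDM member was Pmepa1, a target of TGF-beta signalling, with 1 region 73.0 kb from the gene end (chr2:173348723-173350723). The difference between 8 of 398 YSM genes and 1 of 200 MDM genes did not pass Fisher's exact test (p = 0.284, adjusted p = 1). The log2 odds ratio of MDM over YSM, with the constant added to each count, was -1.53. Counted as regions, 24 of 688 YSM against 1 of 297 MDM regions lay at these genes (Fisher's exact test, adjusted p = 0.0316), but regions of 1 gene are not independent. Against random genes on the same chromosomes, 8 YSM genes stood against 1.46 on average (two-sided permutation p = 2.0e-04, adjusted p = 0.0104). For the MDM list, 1 gene stood against 0.724 on average. Each list is set here against genes at large, so these values do not compare YSM with MDM.

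The engrafted macrophage list, 67 genes fixed for brain macrophages of bone marrow origin, had 3 genes with MDM regions and 0 with YSM regions. They were Mgst1, a microsomal glutathione transferase, with 2 regions (nearest chr6:138139320-138141320), Anxa1, which encodes annexin A1 (chr19:20389663-20391663), and Cd93, a surface glycoprotein of myeloid and endothelial cells (chr2:148442550-148444550), with 1 each. In all 3 the nearest region lay within 1 kb of a gene end. The monocyte list of 40 genes also had 3 genes with MDM regions and 0 with YSM regions: Mgst1, which it shares with the first list, and the SIRP-beta family genes Gm9733 and Sirpb1c. For each list, 3 of 200 against 0 of 398 genes gave p = 0.037 and adjusted p = 0.481 in Fisher's exact test. Against random genes on the same chromosomes, the 3 engrafted macrophage genes stood against 0.579 on average (two-sided permutation p = 0.0416, adjusted p = 0.541). The 3 monocyte genes stood against 0.389 (two-sided permutation p = 0.012, adjusted p = 0.312), and neither list passed. On the YSM side, 0 genes stood against 1.18 and 0.76. Counted as regions, the monocyte list had 5 MDM and 0 YSM regions (Fisher's exact test, adjusted p = 0.0316) and the engrafted macrophage list 4 and 0 (adjusted p = 0.053, which does not pass). Regions of 1 gene are not independent here either: the 2 regions of Mgst1 overlap, and so do the 2 of Gm9733.

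Macrophage transcription factors (83 genes) had 1 gene with an MDM region and 4 with YSM regions (Fisher's exact p = 0.669, adjusted p = 1). Counted as regions these were 1 MDM and 20 YSM regions, 12 of them at Klf12 (Fisher's exact test, adjusted p = 0.053, which does not pass). The MDM gene was Bach2, a transcriptional repressor (chr4:32587351-32589351, 2.24 kb from the gene end). The YSM genes were Klf12, Sall1, Sall3 and Runx1, a regulator of blood cell formation, whose region lay 31.3 kb from an end and inside the gene (chr16:92631740-92633740). No gene of the lineage reporter list had an assigned region in either list.

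None of the 26 gene lists passed an adjusted p of 0.05 in Fisher's exact test, and 2 had an unadjusted p under it, those for engrafted macrophages and monocytes. In simulated lists, 15 genes planted among the YSM genes or 5 among the MDM genes were too few to be called, and the largest real counts were 8 YSM and 3 MDM genes, so the test could not have called counts of this size. The lysosome and phagocytosis list had 1 MDM gene (the scavenger receptor gene Msr1) and 2 YSM genes (the scavenger receptor gene Marco and the phosphatidylserine receptor gene Timd4). The border-associated macrophage list had 1 MDM gene (Cd163). The list of genes induced by interferon had 1 MDM gene (Ifi44l), and that of inflammatory response and chemokines had 1 YSM gene (Tnfrsf1b). Disease-associated microglia, MHC class II presentation, lineage reporters, ribosomal and housekeeping genes, T and NK cells, and B cells made up the 6 lists with no gene in either region list. Markers of neurons (3 genes), oligodendrocytes (2), astrocytes (1) and endothelial cells (1) had YSM regions and no MDM region, and 1 neutrophil marker, Retnlg, had an MDM region.

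Regions of 1 gene fell almost always in 1 list. Among 599 genes with an assigned region, 1, the mitochondrial carrier gene Slc25a26, had regions of both lists, against a mean of 114 when list membership was permuted (range 91 to 138). Of 779 regions with another region within 50 kb, 779 had a nearest neighbour of the same list, against 56.2% in the permutations. Both permutation tests gave p = 1e-04, the smallest they can give. They treat regions as independent, although 33.6% of MDM and 37.8% of YSM regions overlapped another of their own list. Part of the outcome was therefore fixed by overlap. Because the closest opposite pair lay 63.8 kb apart, every neighbour within 50 kb had to be of the same list. With nearby regions joined, 1 gene was shared against 38.4, and 204 of 204 groups had a neighbour of the same list.

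No difference was detected in the share of regions close to the end of a protein-coding gene. In the MDM list 45 regions lay within 1 kb of one (10.5%, 95% interval 7.77 to 13.8), and in the YSM list 90 (10.1%, 8.19 to 12.3), a difference of 0.42 percentage points (95% interval -3.09 to 3.94, Fisher's exact p = 0.846). With genes of all types the difference was 4.08 points and did not pass (Fisher's exact p = 0.0582). Fewer MDM than YSM regions had their midpoint inside a protein-coding gene, 216 (50.5%) against 554 (62.1%), a difference of -11.6 points (-17.3 to -5.93, Fisher's exact p = 6.44e-05). This comparison was chosen after the data were seen, and its exact p rose to 0.00504 with joined regions. Without the 21 MDM regions in the immunoglobulin heavy chain locus, none inside a protein-coding gene, the shares were 53.1% and 62.1% (exact p = 0.00233). Within 100 kb of a gene end lay 69.4% of MDM and 77.1% of YSM regions (Fisher's exact p = 0.00293). That comparison was also chosen later. With joined regions the shares were 70.7% and 76.4%, which no longer passed with fewer units (exact p = 0.0586), and without 21 MDM regions in the immunoglobulin heavy chain locus they were 73.0% and 77.1% (exact p = 0.108).

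The X chromosome carried 0 MDM regions and 1 YSM region, near Cnga2 (chrX:72022738-72024738). With 1 region in all, no split between the lists could have passed Fisher's exact test, so the lists could not be compared there. X holds 4.41% of protein-coding genes. Neither list had a region on Y. Among autosomes, chromosome 10 held 29 of 321 MDM groups (9.03%) and 20 of 615 YSM groups (3.25%), which passed Fisher's exact test after adjustment over the chromosomes (adjusted p = 0.00621). Chromosome 19 held 1 MDM and 16 YSM groups (Fisher's exact test, adjusted p = 0.102). The tests of single autosomes were not planned. They treat groups as independent although neighbouring groups shared a list, so their p-values may be too small.

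**Figure D3:**
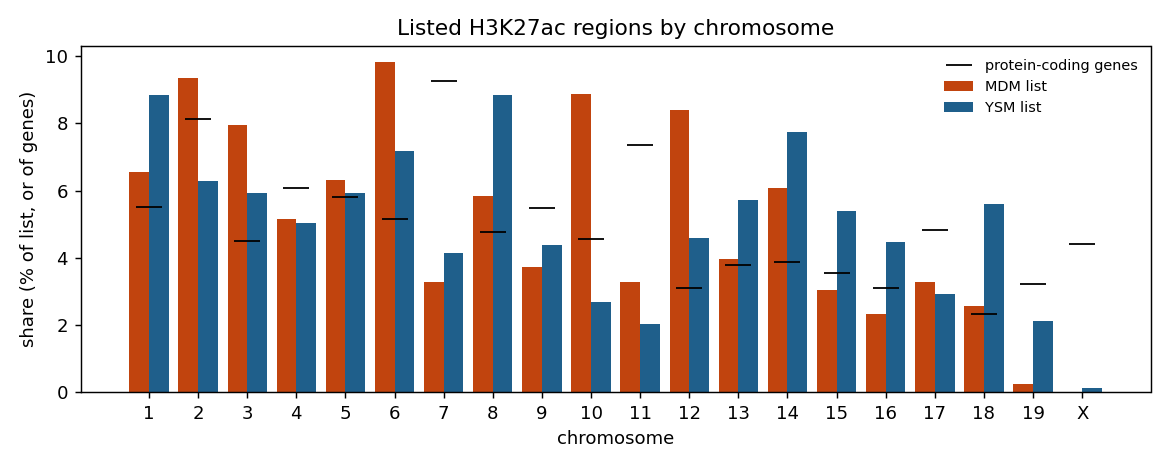
Share of each list's H3K27ac regions on each chromosome (vertical axis, percent; horizontal axis, chromosome), with MDM and YSM bars side by side and a dash for the share of protein-coding genes. Chromosome 10 holds 8.88% of MDM and 2.69% of YSM regions, and X holds 0 MDM regions and 1 YSM region.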

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

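The name number and the score are not measured by any main comparison. The score served to name genes by the rule fixed beforehand, and the name number served for 1 subset in the alternatives; the test of the name number was chosen after the data were seen. Region names end in a whole number of unstated meaning, from 1 to 10 in the MDM list and 1 to 6 in the YSM list. It was 4 or more in 55.4% of MDM regions (237 of 428) and 16.6% of YSM regions (148 of 892), a gap of 38.8 percentage points (Fisher's exact test, two-sided, p = 7.92e-46, over regions that are not independent). The median was 4 in the MDM list and 2 in the YSM list.

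The deposited score was above 1 in 7 MDM and 21 YSM regions. The highest MDM scores were 73 at a region inside Syne1 (chr10:5193953-5195953), 34 at the deoxyribonuclease gene Dnase1l3 (chr14:7993218-7995218), 30 at Gm765 (chr6:98331914-98333914), 27 at Tmtc1 (chr6:148404842-148406842) and 18 inside Cntnap2 (chr6:45270717-45272717). The highest YSM scores were 71 at a region 306 kb from Clint1 (chr11:45545188-45547188), 41 near Pag1 (chr3:9895371-9897371), 34 at Tmem144 (chr3:79851892-79853892), 27 near N6amt1 (chr16:87245312-87247312) and 27 inside Tanc1 (chr2:59842191-59844191). What the score counts is not stated, so these values are given as deposited and compare neither regions nor lists.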

How the results depend on the processing

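No paired analysis was possible because the lists hold no values per library, and for the same reason no library was left out; read depth is unknown. The motif comparison and a better-scored part of each list were not run, the first for lack of sequence and the second because nearly all scores equal 1. Random positions, nearest gene bodies, the first part in file order, name numbers of 2 or more and lists without single loci, and joined regions for neighbours and gene bodies, were chosen after seeing the data. The number of gene lists passing, 0, became 2 with regions as the unit (microglia identity and monocyte), where regions of 1 gene are not independent. It became 1 against random genes and 1 against random positions (microglia identity in YSM, 8 against 1.81, permutation, adjusted p = 0.0312). There the comparison set differs by construction, and YSM is not compared with MDM. It was 0 under the other assignments and subsets, where no list held more than 11 YSM genes or 4 MDM genes. In simulated lists of 598 genes, 15 planted YSM genes or 5 planted MDM genes were called in 0 of 100 draws. Counts this small could not have passed, so the 0 does not measure dependence on the assignment or subset. The log2 odds ratio of microglia identity, with the constant added, stayed between -2.71 and -1.41 over all gene-based settings, with adjusted p from 0.62 to 1. The value of -2.71 rests on 0 MDM genes within 10 kb. Those of the engrafted macrophage and monocyte lists ranged from 2.54 to 3.89 and from 2.17 to 3.89. In the first part in file order each of these 2 lists had 1 MDM gene and 0 YSM genes (Fisher's exact p = 0.342). Genes with regions of both lists numbered 0 within 10 kb, 8 with no distance limit, 25 with extended domains and 4 with nearest gene bodies, against permutation means of 35.4, 165, 295 and 130 (each p = 1e-04, the smallest possible). The excess of MDM over YSM regions near gene ends turned to -2.22 percentage points with a 5 kb window (Fisher's exact p = 0.367) and -0.61 from region edges (p = 0.794), and rose from 0.42 to 4.08 with all gene types (p = 0.0582). It passed no test at any setting, and the cause was not tested. Same-list neighbours were 98.6% within 200 kb and 100% at the other settings. In all, 47 values under alternatives to the main results, those with all gene types included, kept their direction and their side of any threshold. Another 7 moved and 2 reversed direction. The 47 do not measure stability, because many could not have changed. Among them are 5 for the X share, where no outcome could pass, and gene list tests that could not call counts of this size. Others are counts, widths and overlaps without a threshold, and gene results without loci whose regions had no assigned gene.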

Other observations

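Fisher's exact tests of the gene lists and the comparison with random genes were planned. The other permutation, placement, shift and binomial tests in this part were chosen after the results were seen. Single members of other fixed lists had regions that the comparisons did not name. The homeobox gene Hoxb4, of the Hox and haematopoietic origin list, had 2 MDM regions, the nearest 0.497 kb from a gene end (chr11:96317764-96319764), and the dipeptidyl peptidase gene Dpp4 had 2 MDM regions (chr2:62411367-62413367). The cell cycle kinase gene Cdk6 had 1 MDM region (chr5:3433080-3435080), whereas Cdkn2a, which encodes cell cycle inhibitors, had 1 YSM region (chr4:89269763-89271763). Of the axon guidance and synapse list, Plxna4 had 2 MDM regions, and Efnb2, Sema6a, Robo2 and Slit1 had 3, 3, 1 and 1 YSM regions. Of the TGF-beta list, Smad1 and Acvr2b had 1 YSM region each, both inside the gene. In the lipid list, Apoc4 and Msr1 were on the MDM side and Osbpl8 on the YSM side. None of these lists passed its test.

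The pair of opposite regions that lay closest was on chromosome 7, with the MDM region 2.49 kb from Apoc4 (19682946 to 19684946) and the YSM region 132 bp from an end of Nectin2 (19748705 to 19750705). No region of either list was assigned to Ms4a3, which drives Cre in these mice, the nearest lying 4263 kb away, and the nearest to the Rosa26 reporter locus lay 2604 kb away. Lists were unevenly spread over chromosomes (permutation p = 7.5e-04, joined groups treated as independent, although neighbouring groups shared a list). The first region of the MDM list belonged to a pile of 4 on chromosome 2 (98661638 to 98668131), 1033 kb from the nearest protein-coding gene end, and the first of the YSM list lay inside Lars2 (chr9:123460989-123462989). Neither was checked against a list of problem regions of mm10, so a mapping artefact is not excluded at either.

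The MDM list held 21 regions, 4.91% of the list, in the immunoglobulin heavy chain locus of chromosome 12 (113256204 to 116009954), all between 114990167 and 115875266, and the YSM list held 0. Joined, these were 14 MDM and 0 YSM groups. When list membership was permuted over all groups, no window of the length of the locus anywhere in the genome held more than 10 MDM groups without a YSM group, against 16 in the window that starts at these regions (permutation p = 1e-04, the smallest possible). That permutation treats groups as independent, which they are not: 204 of 204 groups with a near neighbour shared its list, against 54.9% in the permutations. It therefore excludes only a split of the groups 1 by 1. Chance for a stretch that goes to 1 list together is not excluded. The light chain and T cell receptor loci held 1 MDM region, in the beta locus, and 0 YSM regions. Of the 21 midpoints, 17 lay within 1 kb of a V segment, against 3.61 on average when the set was shifted along the locus 10000 times (one-sided permutation p = 0.0011), a pattern that reads shared between similar V segments could give and that activity at V segments could give too. B cells in the MDM sort remain open: 0 of 16 B cell marker genes, 1 of which another list also holds, had an MDM region, but lists of differential regions hold no levels, and the different origin of the cells is a further explanation that was not tested.

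Neural marker genes with regions were all in the YSM list: Celf4, Snap25 and Grin2a for neurons, Mog and Mbp for oligodendrocytes and Slc1a3 for astrocytes, with 14 regions. None of the 3 lists passed Fisher's exact test between the region lists (p = 0.554, 0.554 and 1). Against random genes on the same chromosomes, 3 neuron genes stood beside 0.46 on average (two-sided permutation p = 0.0208, adjusted p = 0.36). The 2 oligodendrocyte genes stood beside 0.347 (two-sided permutation p = 0.0854, adjusted p = 0.74) and the 1 astrocyte gene beside 0.335 (p = 0.581). Against random placement of the YSM groups on the same chromosomes, 3 neuron genes stood beside 0.94 on average (two-sided permutation p = 0.125), 2 oligodendrocyte genes beside 0.383 (p = 0.112) and 1 astrocyte gene beside 0.458 (p = 0.752), each with an adjusted p of 1, so the large territories of these genes stay open as the cause. Other brain cells in the YSM sort may contribute and cannot be told apart from regulation in the macrophages: 0 of the 58 marker genes had a YSM region within 1 kb of a gene end, yet promoters shared by both groups would not be listed. None of the 58 is in another fixed list, the cells were sorted, and the lists give no levels.

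Of 936 joined groups, 1 lay on X, where the X share of protein-coding genes would give 41.3 (two-sided exact binomial p = 4.28e-17). That share is a poor guide on autosomes too, where groups ranged from 0.32 times the number it gives on chromosome 11 (22 against 68.8) and 0.415 times on chromosome 7 (36 against 86.8) to 2.15 times on chromosome 18. At the rate of chromosome 11, X would still hold 13.2 groups, above the upper exact Poisson 95% limit of 5.57 for 1 group. The binomial test and this limit treat groups as independent, so they exclude only counting error at these rates. Variation between chromosomes beyond counting error is not covered. Removal of X from both lists as a whole is excluded by the 1 X region that remains. A lower read depth on X, filtering by the authors before the test, or a true lack of differences on X stay open, since regions tested and not listed are unknown. The sex of the animals is not in the labels, and no biological explanation was tested.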
